A study of Danio rerio with 17 samples.

How the data were processed

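Total RNA was extracted with Trizol from single midbrains of 17 adult male zebrafish. Per the labels, double-stranded cDNA was made with random hexamers, labelled with Cy3 and hybridised to NimbleGen expression arrays. The labels give no array slide or scan date, so batches of arrays could not be looked for. The label code of Pargana deficient fish 3 has a different letter from those of the other Pargana fish, and its array was kept in the Pargana group, whose side of the first principal component it shares.

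The deposited values are log2 expression values per Ensembl gene, which the authors made by RMA (background correction, normalization between arrays and summary of the probes) with the Zv9 genome build. No software version is stated. They were used as deposited. The table held 15649 features, and 1 of them, which names no gene, was left out. Of the remaining 15648 gene identifiers 13251 (84.68%) have a symbol, 12463 symbols are distinct and 1559 identifiers share a symbol with another. No value was missing. Positions of genes on Zv9 were not used here. The RefSeq annotation of the GRCz12tu assembly was used for synonyms and for the order of 10573 genes along the chromosomes.

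Differences were tested with limma 3.58.1 in R 4.3.3, with a mean for each of the 6 groups, all 17 arrays in the fit and empirical Bayes moderation of the variances (11 residual and 2.84 prior degrees of freedom). P values were adjusted by the method of Benjamini and Hochberg over all genes of a comparison, with a threshold of 0.05, and all tests were two-sided. The comparisons were the population difference averaged over the diets, the 3 pairs of diets within each population, the deficient and the supplemented diet against control averaged over both populations, and the interaction of population and diet as a moderated F test. The gene lists, the comparisons with their limma and camera tests and the rule for named genes were fixed before the data were examined; later choices are named where they are given.

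Named genes were those with a single symbol, each represented by its feature of highest mean. For the population difference they were the 12 largest differences in each direction among genes past the threshold with the same sign in all 3 diets. For a diet comparison they were the 10 largest changes in each direction past the threshold and, where fewer than 8 passed, the genes of smallest p up to 8. For the interaction they were the 8 genes of smallest p. Selenoproteins with an unadjusted p under 0.05 were named as well, with gpx1a, selenop, selenow1, gpx4b and selenoh for reference, and list members past the threshold or up to 4 of the largest values. Features without a symbol, and the features that set control fish apart, were singled out after their values were seen. Some genes that the rule takes are not reported here.

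Shifts of 29 gene lists were tested with camera of limma, with a preset correlation between genes of 0.01 and 1 feature per gene, in 11 comparisons, adjusted over all 319 tests. Camera with an estimated correlation and fry were run beside it. Of 1025 list entries 755 were matched, by symbol or older symbol, RefSeq synonym or base symbol. This matching rule was settled after the annotation was seen, and 1 wrong alias was dropped. The feature named GPX4 was matched by its base symbol. A list score per array is the mean over its genes of the value minus the gene's mean over all arrays. Correlations between the populations' log2 changes were compared with 100 permutations of the diets within populations. Overlap of comparisons that share control fish was compared with 100 simulated sets of unchanged groups.

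The alternatives were quantile normalization again, arrays centred on their medians, the lowest quartile of mean value left out, 1 feature per symbol, trended and robust variance moderation, array weights, a model without interaction, fits of the 2 groups or of the population compared, and leaving out each array in turn. For lists they were the estimated correlation, fry and a trended variance. Added after the data were seen were scores of 4 marker lists as covariates and, for the population difference, a fit without the 5 arrays with a score above 0.9 in any of them. Tables and figures were made with python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

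The tests were checked on simulated data with 15648 genes, of which a separate set of 200 was changed for each comparison named here. False calls were counted among the genes changed for none of them. For the population difference 65.7%, 94.0% and 98.5% of genes changed by 0.5, 1 and 2 log2 units were recovered, with 16 false calls. For deficient against control Pargana fish 7.46%, 46.3% and 92.4% were recovered, with 6 false calls, and for supplemented against control Transgenic Mosaic 1 fish 17.9%, 53.7% and 92.4%, with 4 false calls. With no change 0 of 319 list tests passed, and a shift of 0.5 in the muscle list was called. Genes were drawn independently in these simulations, so the list check holds no correlation between genes and does not give the false calls on real arrays. The real arrays with permuted diets gave a median of 35 calls in 290 list tests.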

Results

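Gene expression was measured in the midbrains of 17 individual male zebrafish, 1 year old, with single-colour (Cy3) NimbleGen arrays. The fish came from 2 populations, named Pargana and Transgenic Mosaic 1 in the labels, and had eaten 1 of 3 diets for 10 weeks. The diets held selenium, given as selenomethionine, at 0.46 ppm (deficient), 1.7 ppm (control) or 3.1 ppm (supplemented). Each combination of population and diet had 3 fish, except Pargana on the control diet, which had 2. Every array is a separate fish, so the spread within a group holds variation between individuals. It also holds variation from dissection, RNA preparation and hybridisation, which 1 array per fish cannot separate. The deposited log2 values covered 15648 genes and ran from 3.48 to 15.49, with array medians between 9.62 and 9.73. The number of arrays limits the precision of every comparison.

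Population separated the arrays more than diet did. The first principal component held 26.0% of the variance and placed all 8 Pargana arrays between 18.2 and 35.4 and all 9 Transgenic Mosaic 1 arrays between -29.8 and -13.1. The second component held 9.81% of the variance and had Pargana control fish 1, at 43.3, and Pargana control fish 2, at -24.4, near its opposite ends. These 2 fish are the whole Pargana control group. Their values correlated at r = 0.974 across genes, against 0.980 to 0.991 for the other pairs of fish of a group, and the SD of the difference between them was 0.62 log2 units.

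**Figure D1:**
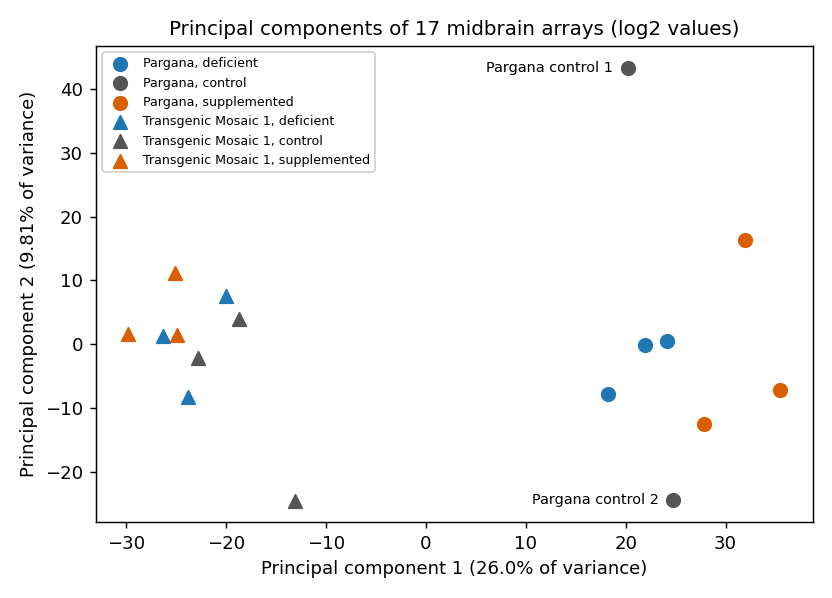
Principal components of the log2 values, with component 1 on the x axis and component 2 on the y axis; each point is an array, circles are Pargana, triangles are Transgenic Mosaic 1, and colours mark the diet. Component 1 (26.0% of the variance) parts the populations, and the 2 Pargana control fish lie at 43.3 and -24.4 on component 2.

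The first comparison asked how the midbrain transcriptomes of the populations differ, averaged over the diets. Transgenic Mosaic 1 had lower levels of si:ch211-137i24.12 (ENSDARG00000094537), at 5.95 ± 0.62 (SD, n = 9) log2 units against 11.56 ± 0.34 (SD, n = 8) in Pargana, and of chia.4, which encodes an acidic chitinase, at 4.49 ± 0.20 (SD, n = 9) against 9.12 ± 0.33 (SD, n = 8). The differences were -5.64 (SE 0.23, limma adjusted p = 4.16e-09) and -4.61 (SE 0.13, limma adjusted p = 6.72e-11). Transgenic Mosaic 1 had higher levels of si:dkey-56d12.4 by 3.71 (SE 0.57), of RRH, which encodes the retinal pigment epithelium opsin peropsin, by 3.32 (SE 0.51), and of TYMS, the thymidylate synthase of DNA precursor synthesis, by 2.65 (SE 0.21). In all, 2089 genes passed an adjusted p of 0.05 in limma, 1002 higher and 1087 lower in Transgenic Mosaic 1, and 346 of them differed by more than 1 log2 unit. Of the 2089 genes, 1998 (95.6%) had the same sign within all 3 diets. They were called on the average of the same 3 differences, which favours agreement in sign, so this share is no separate test. For 303 genes every array of one population lay above every array of the other, 154 of them higher in Transgenic Mosaic 1, where chance gives 0.00823% of genes.

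Other genes higher in Transgenic Mosaic 1 were fhad1 (3.16), UBE2G1, a ubiquitin-conjugating enzyme (2.83), pimr108 (2.70), the receptor P2RY8 (2.58), PPP1R42 (2.56), the small GTPase rab11al (2.45), zp3b, a glycoprotein of the egg coat (2.43), tatdn2 (2.39), and MMAB, an enzyme of vitamin B12 metabolism (2.35). Genes lower in Transgenic Mosaic 1 included the growth factor GDF2 (-3.10), the myosin heavy chain myh6 (-3.09), ssuh2.1 (-2.89), TSHB, the beta subunit of thyrotropin (-2.84), TTLL2 (-2.79), AGMO, which cleaves ether lipids (-2.47), tubb1 (-2.45), ptpdc1b (-2.43) and the hexose-binding lectin hbl2 (-2.42). Another feature with the symbol myh6 had the opposite sign. TSHB was at 3.69 and 3.67 in Transgenic Mosaic 1 supplemented fish 2 and 3, where the lowest values of the arrays were 3.68 and 3.67, and it was highest in Pargana control fish 2 (9.43) and supplemented fish 3 (9.13), so the size of its difference is uncertain. The difference in UBE2G1 came from low values in the Pargana control fish, as given below for the diets. Within single diets, 149 genes passed between the control fish, 225 between the deficient fish and 606 between the supplemented fish. With scores of muscle, eye and pineal, pituitary and macrophage marker genes as covariates, a setting chosen after the data were seen, 222 genes passed, 182 of them among the 2089, and 12 of the 24 genes of largest difference lost the call. Without the 5 arrays that had a high score in any of these lists, which include both control and 2 of the 3 supplemented Pargana fish, in a model of population plus diet, 779 genes passed, 647 of them shared, and 7 of the 24 lost the call, among them UBE2G1 at 0.68; without Pargana control fish 2 alone, AGMO and P2RY8 lost it, and without Pargana control fish 1, tubb1 did (-2.00).

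Of 29 gene lists fixed before the data were examined, the muscle list differed between the populations. It was lower in Transgenic Mosaic 1, with a median of -0.54 over 19 genes and 16 of them below 0 (camera, adjusted p = 3.16e-04). The adjusted p was 0.992 with an estimated correlation. The muscle score, defined below, was 1.41 and 0.90 in Pargana supplemented fish 1 and 3 and 0.63 in Pargana deficient fish 2. It was -0.18 and -0.22 in the Pargana control fish and -0.34, -0.48 and -0.47 in the Transgenic Mosaic 1 control fish. In this list 6 genes fell on their own, 9 when adjusted over the list alone, among them TNNC2, a fast-muscle troponin (-1.28), TNNT3 (-1.58), the parvalbumin pvalb4 (-1.70) and the calcium pump atp2a1 (-1.71). Single members of other lists passed too. Of all genes 13.35% passed for this comparison, so a few members that pass do not set a list apart. In the pituitary and hypothalamus list 3 of 22 genes fell, TSHB, smtla (-1.18) and pomcb (-0.31), with a list median of -0.37 and an adjusted p of 0.0961. In the eye and pineal list RPE65, the retinoid isomerase of the visual cycle, rose (1.27) and the lens crystallin CRYAA fell (-1.96). In the interferon and antigen presentation list IFIH1, a sensor of viral RNA, rose by 1.56, RSAD2 by 0.78 and tapbpl by 0.95, while tapbp.1 fell (-1.65).

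None of the following lists passed in camera for the population difference, and the members named are those that passed alone. In the methionine cycle and transsulfuration list SHMT1, a serine hydroxymethyltransferase of folate metabolism, rose by 2.14, CSAD by 0.50 and AHCYL1 by 0.32, and 17 of 21 genes did not pass. In the antioxidant and glutathione list NQO1, a quinone reductase, rose by 0.72 and TXN2 by 0.32, out of 36 genes. The oxidative phosphorylation list had a fall of cox7a1, the heart and muscle isoform of a cytochrome c oxidase subunit (-2.29), among 59 genes whose median was 0.00. CRYM, which binds thyroid hormone in the cytosol, rose by 1.38 in the thyroid hormone list. In the proliferation and neurogenesis list CCNB1 rose by 0.89 and tubb5 by 0.60 beside TYMS, and in the myelin list plp1b rose by 0.47. In the monoamine neuron list DBH, which makes noradrenaline, rose by 0.75 and DDC by 0.44. In the steroid and stress axis list ESR2, an oestrogen receptor, rose by 0.79 and STAR by 0.89, and hsd3b1 fell (-1.64). With fry's mixed test, which asks whether genes of a list change in either direction, 18 of the 29 lists passed for the population difference. That test does not compare a list with the other genes, of which many passed too (13.35% of all genes). It therefore does not show that these lists differ more than other genes.

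Selenoproteins were examined because diet selenium was the variable. No selenoprotein passed an adjusted p of 0.05 in limma in any comparison between diets. In Pargana, gpx1a, which encodes a glutathione peroxidase, had 11.04 ± 0.51 (SD, n = 3) log2 units on the deficient diet and 11.73 ± 0.30 (SD, n = 2) on the control diet, a difference of -0.68 (SE 0.26, limma adjusted p = 0.610). On the supplemented diet it had 11.27 ± 0.11 (SD, n = 3), -0.46 (SE 0.26) from control. In Transgenic Mosaic 1 the corresponding gpx1a differences were -0.33 (SE 0.23) and -0.45 (SE 0.23). Averaged over both populations, gpx1a differed from control by -0.50 (SE 0.18) on the deficient and by -0.45 (SE 0.18) on the supplemented diet, at limma adjusted p of 0.666 and 0.852. The gene selenos, whose protein serves the removal of misfolded proteins from the endoplasmic reticulum, had 10.36 ± 0.04 (SD, n = 3) in supplemented Pargana fish, 10.89 ± 0.12 (SD, n = 3) in deficient and 11.15 ± 0.17 (SD, n = 2) in control fish. Its difference between supplemented and control Pargana fish was -0.80 (SE 0.14, limma adjusted p = 0.0919 over all genes), and it was the 1 selenoprotein that passed when adjusted over the list alone; it also passed that way for supplemented against deficient Pargana fish, at -0.53 (SE 0.13). In Transgenic Mosaic 1 the selenos difference between supplemented and control fish was 0.12.

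The largest difference from control in the selenoprotein list was that of selenow2b in supplemented Pargana fish, at 6.66 ± 0.21 (SD, n = 3) against 5.47 ± 0.24 (SD, n = 2), which did not pass (1.19, SE 0.61, limma adjusted p = 0.883) and is given after its values were seen. The same difference in Transgenic Mosaic 1 was -0.31 (SE 0.54). Between deficient and control Pargana fish the differences were -0.16 (SE 0.15) for selenop, which encodes the selenium transport protein of plasma, 0.20 (SE 0.15) for selenow1 and -0.17 (SE 0.19) for GPX4, which reduces lipid hydroperoxides and whose symbol names neither of the zebrafish copies. In Transgenic Mosaic 1 they were -0.06 (SE 0.14), -0.24 (SE 0.14) and -0.03 (SE 0.17). The gene selenoh was not matched to a measured gene. The 18 measured selenoproteins had a median change of -0.16 in deficient and -0.07 in supplemented Pargana fish against control, and of -0.04 and -0.09 in Transgenic Mosaic 1. None of these 4 medians passed (camera, adjusted p 0.509, 0.576, 0.836 and 0.722). The 6 genes of the list of selenoproteins most sensitive to selenium supply had medians of -0.03 and -0.02 in Pargana and of -0.06 and -0.12 in Transgenic Mosaic 1 for the same comparisons. The 7 genes of the selenocysteine machinery list, which includes LRP8, a receptor for selenoprotein P, had medians of -0.11, -0.06, 0.03 and 0.03. Between the populations selenow1 (0.34) and selenot1b (0.28) were higher and SEPHS2 (-0.29) and SEPSECS (-0.48), both of selenocysteine synthesis, were lower in Transgenic Mosaic 1, while the median of the 18 selenoproteins was -0.01.

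**Figure D2:**
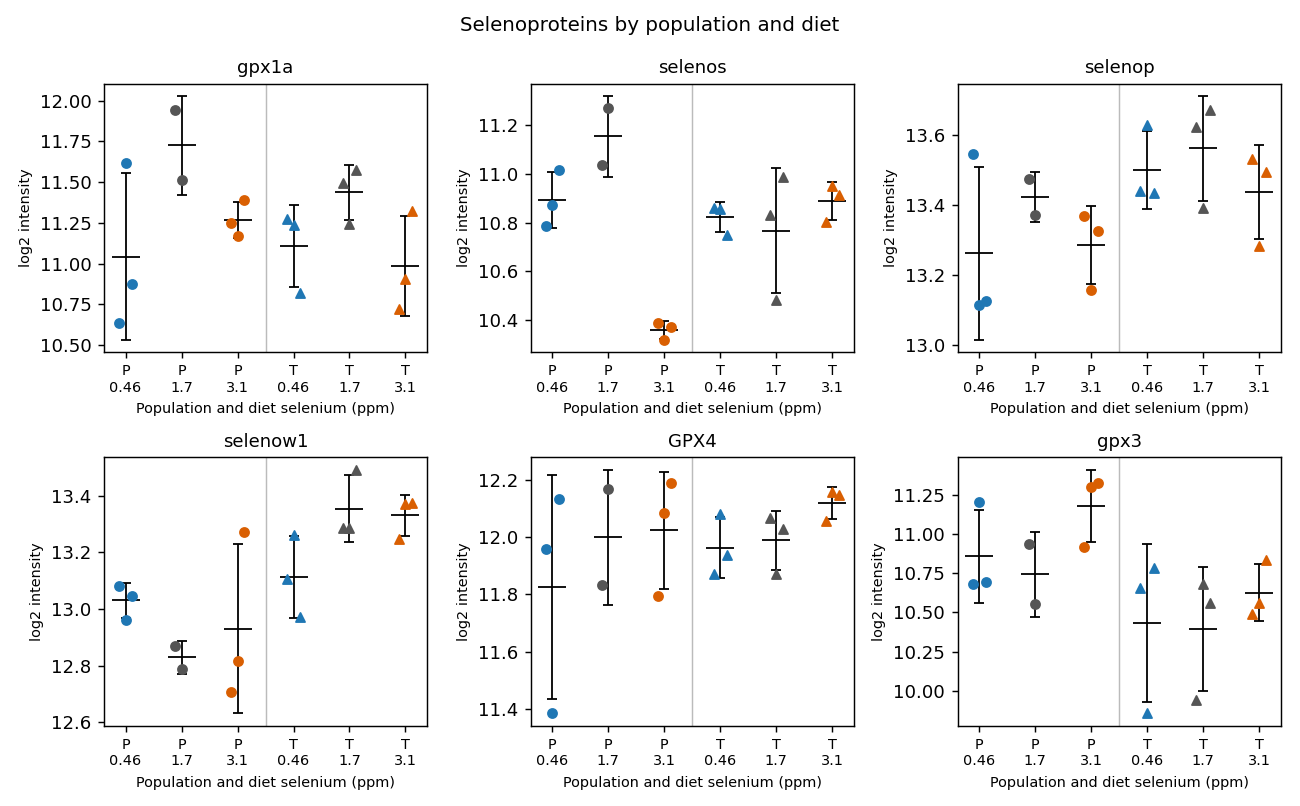
Log2 intensity (y axis) of selenoproteins by population (P, Pargana; T, Transgenic Mosaic 1) and diet selenium in ppm (x axis); points are single fish, horizontal lines are group means and bars are SDs. The selenos values of supplemented Pargana fish (10.36 ± 0.04) lie below those of control Pargana fish (11.15 ± 0.17), and gpx1a is highest in Pargana control fish (11.73 ± 0.30).

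The Pargana diets were compared next. On the deficient diet, UBE2G1 was at 12.23 ± 0.90 (SD, n = 3) log2 units against 5.56 ± 0.34 (SD, n = 2) on the control diet, a rise of 6.67 (SE 0.35, limma adjusted p = 3.65e-07). On the supplemented diet it was at 11.73 ± 0.17 (SD, n = 3), a rise of 6.17 (SE 0.35, limma adjusted p = 1.04e-06). The gene sun1a, which encodes a protein of the inner nuclear membrane, rose by 1.33 (SE 0.17) on the deficient and by 1.18 (SE 0.17) on the supplemented diet. On the deficient diet si:ch211-283g2.1 fell (-5.72, SE 0.85) and so did pmaip1, which encodes the pro-apoptotic protein Noxa (-1.67, SE 0.24); they lost these calls in 7 and 4 of 17 single omissions. The unnamed features ENSDARG00000018298 (-2.35 and -2.16) and ENSDARG00000091965 (2.15 and 2.49) passed on both diets, and ENSDARG00000093414 (2.37) on the supplemented diet; they are named here after their values were seen. ENSDARG00000091965 lost the deficient call without Pargana control fish 1 (2.01). On the supplemented diet ENSDARG00000018298 (-1.90 and -2.29) and ENSDARG00000093414 (2.37 and 2.37) lost theirs without Pargana supplemented fish 1 or 3, and ENSDARG00000093414 also without Pargana control fish 1 (2.45). In all, 6 genes passed for deficient against control, 3 higher and 3 lower, and 5 for supplemented against control, 4 higher and 1 lower, with 1103 and 941 genes at an unadjusted p under 0.05 where 782.4 are expected by chance.

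The next genes by p for the deficient diet, none of which passed, were EPHX2, an epoxide hydrolase (-1.33), acte1 (2.41), emilin1a (-1.03) and CLIC3 (-1.09). For the supplemented diet they were tnfsf10l3 (-1.12), zgc:86896 (3.24), si:ch211-283g2.1 (-4.89), HSF2BP (4.05), selenos and CHRNA2, a nicotinic receptor subunit (-0.65). Without Pargana control fish 2, 198 genes passed for the deficient and 162 for the supplemented diet; without Pargana control fish 1, 3 passed for the deficient diet and sun1a lost its call on both, as it did for the supplemented diet without supplemented fish 1 or 3 or Transgenic Mosaic 1 control fish 1. Without Pargana supplemented fish 2 the counts were 13 and 43, the supplemented count was 2 without supplemented fish 1 or 3 and between 8 and 12 without Pargana deficient fish 2 or 3 or Transgenic Mosaic 1 control fish 2 or 3, and with the Pargana arrays fitted alone 2 and 1 genes passed.

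Between supplemented and deficient Pargana fish no gene passed in limma, with 1018 genes at an unadjusted p under 0.05 and a smallest adjusted p of 0.222. The smallest p belonged to pmaip1, which was 1.39 (SE 0.21) higher on the supplemented diet, at 6.47 ± 0.43 (SD, n = 3) against 5.08 ± 0.08 (SD, n = 3). It was followed by hsh2d (0.91), exoc3l4 (1.63), ghdc (-1.11), BPNT1 (0.74), the collagen COL12A1 (1.36), SLC18A3, the vesicular acetylcholine transporter (-1.09), and C9H2orf49 (-0.97). Without Pargana supplemented fish 2, 16 genes passed, with pmaip1, COL12A1 and SLC18A3 among them; 5 passed without Pargana deficient fish 2, 3 without fish 1 and 2 without fish 3 or without Transgenic Mosaic 1 control fish 3.

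In Transgenic Mosaic 1, the gene ENSDARG00000095735, which has a clone name only, was at 9.32 ± 0.16 (SD, n = 3) log2 units on the deficient and 8.74 ± 0.26 (SD, n = 3) on the supplemented diet, against 13.59 ± 0.11 (SD, n = 3) on the control diet. The falls were -4.27 (SE 0.15, limma adjusted p = 2.42e-09) and -4.85 (SE 0.15, limma adjusted p = 4.26e-10). The gene si:dkey-58f10.8 fell on both diets (-2.01 and -2.21), and so did the unnamed ENSDARG00000078938 (-4.05 and -4.00). For the deficient diet 4 genes passed, all lower than control, with 730 at an unadjusted p under 0.05. The next by p, which did not pass, were trim35-31 (0.96), the elongation factor eef2a.2 (-1.74), AIF1L (0.69), si:dkey-251i10.2 (-2.53) and CIAO2B (-0.64). Without Transgenic Mosaic 1 deficient fish 2, 10 genes passed, with trim35-31 and eef2a.2 among them.

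The supplemented diet had 13 genes past the threshold in Transgenic Mosaic 1, 5 higher and 8 lower than control. The rises included mdh1b, a malate dehydrogenase, at 9.14 ± 0.22 (SD, n = 3) against 6.63 ± 0.11 (SD, n = 3), a change of 2.52 (SE 0.38, limma adjusted p = 0.0158). Smaller rises were those of brat1, which acts in the response to DNA damage (1.11, SE 0.14), si:ch73-191k20.4 (1.00, SE 0.13), cox16, an assembly factor of cytochrome c oxidase (0.94, SE 0.15), and the unnamed ENSDARG00000063359 (1.55, SE 0.16). Beside the genes above, tbx16l, a T-box transcription factor (-1.58, SE 0.23), ALX1, a homeobox transcription factor (-1.16, SE 0.16), si:dkey-222f2.1 (-1.04, SE 0.13) and the unnamed ENSDARG00000086621 (-3.20, SE 0.53) fell. In the order of 10573 genes mdh1b, si:ch73-191k20.4 and brat1 were at places 35, 59 and 87, on chromosome 1. ENSDARG00000095735 and tbx16l were at 2229 and 2285, on chromosome 5. The genes cox16, ALX1 and si:dkey-222f2.1 were on chromosomes 13, 18 and 22. These places were looked at after the calls were seen, and whether the calls share a chromosome segment was not tested at this distance. With array weights 34 genes passed, and without Transgenic Mosaic 1 deficient fish 2, 26 did, while 8 passed without supplemented fish 1 and 5 with the Transgenic Mosaic 1 arrays fitted alone. The call of mdh1b ended without any single Transgenic Mosaic 1 control or supplemented fish. That of tbx16l ended without control fish 1 or 3 or supplemented fish 1 or 2, that of ALX1 without control fish 2 or supplemented fish 1 or 3, and that of cox16 in 8 of 17 single omissions. Over all 17 omissions the values ran from 2.42 to 2.64, -1.76 to -1.33, -1.30 to -1.04 and 0.81 to 1.07. With the Transgenic Mosaic 1 arrays fitted alone mdh1b, brat1, si:ch73-191k20.4, cox16, tbx16l, ALX1, si:dkey-222f2.1 and ENSDARG00000086621 lost their calls, and ENSDARG00000086621 also lost it in 11 of 17 single omissions (-3.47 to -3.01 over all 17).

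Between supplemented and deficient Transgenic Mosaic 1 fish 1 gene passed, ENSDARG00000063359, which was 1.21 (SE 0.16, limma adjusted p = 0.0326) higher on the supplemented diet, at 6.05 ± 0.13 (SD, n = 3) against 4.84 ± 0.15 (SD, n = 3). The next by p were brat1 (0.78), mdh1b (1.89), slc25a51a (-0.81), SCO2, which serves the assembly of cytochrome c oxidase (-0.68), btbd16 (-0.54), si:ch73-191k20.4 (0.57), si:ch211-216l23.2 (-0.55) and FOXQ1 (-0.94), none of which passed. At an unadjusted p under 0.05 there were 522 genes, fewer than the 782.4 expected by chance. The count was 0 in 7 of 9 other settings, such as quantile normalization again or trended and robust variance moderation, and 0 without any of 10 single arrays. It was 2 without deficient fish 1. Without supplemented fish 3, 2 other genes passed, both lower, so ENSDARG00000063359 lost its call in 11 of 17 single omissions (1.14 to 1.29 over all 17). In 2 of the 7, the lowest quartile left out and 1 feature per symbol, this feature is not tested.

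Averaged over both populations, 5 genes passed for deficient against control, 1 higher and 4 lower, and 7 for supplemented against control, 2 higher and 5 lower. They included UBE2G1 (3.47 and 3.19), ENSDARG00000095735 (-2.10 and -2.37), ENSDARG00000018298 (-1.51 and -1.59), ENSDARG00000078938 (-1.69 and -1.80), and si:dkey-58f10.8 (-1.08), si:dkey-222f2.1 (-0.68) and ENSDARG00000063359 (1.05) for the supplemented diet. UBE2G1 took its change from Pargana, and ENSDARG00000095735, ENSDARG00000078938 and si:dkey-58f10.8 took theirs from Transgenic Mosaic 1, so these averages describe neither population. The call of si:dkey-222f2.1 ended in 6 of 17 single omissions (-0.73 to -0.62 over all 17). Next by p for the deficient diet were si:dkey-58f10.8 (-0.83), CHRNA2 (-0.41), RNLS (0.62), exoc3l4 (-1.18) and FRMD6 (-0.38), and for the supplemented diet CHRNA2 (-0.46), emilin1a (-0.72) and WFS1, a protein of the endoplasmic reticulum (0.79), none of which passed. A second feature with the symbol CHRNA2 had the opposite sign for the deficient diet. In a model of population plus diet without interaction, 0 genes passed in either comparison, and without Pargana control fish 2, 98 and 90 passed. For the supplemented diet the count was 11 without Pargana deficient fish 1, 15 without deficient fish 2, 14 without supplemented fish 2 and 13 without Transgenic Mosaic 1 deficient fish 2.

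The interaction asked whether the diets changed genes differently in the 2 populations. In the moderated F test of limma 6 genes passed, with 881 at an unadjusted p under 0.05. They included ENSDARG00000095735 (adjusted p = 1.41e-07), UBE2G1 (1.41e-05), ENSDARG00000078938 (1.41e-05), si:dkey-58f10.8 (0.00319) and ENSDARG00000091965 (0.0103). In each of these the control fish of 1 population stood apart from that population's other fish. UBE2G1 was at 5.32 and 5.80 in the 2 Pargana control fish and between 11.56 and 13.26 in all other fish. The gene ENSDARG00000095735 was between 13.50 and 13.71 in the 3 Transgenic Mosaic 1 control fish and between 8.53 and 9.63 in all other fish. ALX1 (0.0538), sun1a (0.0608), pmaip1 (0.0748) and GFI1 (0.107) came next and did not pass. Without Pargana control fish 2, 87 genes passed, without Pargana supplemented fish 2, 13, and without deficient fish 2 of either population, 11. Without Pargana control fish 1, si:dkey-58f10.8 (0.0513) and ENSDARG00000091965 (0.137) lost their calls.

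Gene lists were then compared between diets, in camera tests whose adjusted p cover 319 combinations of list and comparison. Muscle genes rose in supplemented Pargana fish, with a median of 1.16 over 19 genes and 15 of them above 0 (adjusted p = 3.07e-11). No member rose when adjusted over all genes and 12 rose when adjusted over the list alone, among them TNNT3 (2.44), myhc4 (2.25), pvalb4 (2.14) and mybpc2b (2.07). The adjusted p was 0.992 with an estimated correlation. The muscle score, the mean of its genes each centred on its mean over all arrays, was 1.41 in Pargana supplemented fish 1, 0.90 in fish 3 and 0.37 in fish 2, against -0.18 and -0.22 in the Pargana control fish. In deficient Pargana fish the muscle median was 0.44 (adjusted p = 0.00171), and the call ended without Pargana deficient fish 2, at 0.26, or without Pargana control fish 2, at 0.52. Between supplemented and deficient Pargana fish it was 0.48 (adjusted p = 7.62e-04), and it ended without Pargana supplemented fish 1, at 0.25, or without Pargana deficient fish 1, at 0.37. Averaged over both populations the muscle medians were 0.19 for the deficient diet, a call that ended without Pargana control fish 2 or deficient fish 2, and 0.71 for the supplemented diet. With an estimated correlation all of these adjusted p were 0.992.

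Microglia and macrophage genes fell in Pargana on both diets, with medians of -0.78 on the deficient (25 of 27 genes below 0, adjusted p = 5.80e-06) and -0.48 on the supplemented diet (25 of 27, adjusted p = 2.24e-04). No member passed alone. The lowest changes on the deficient diet were in c1qb, a complement component (-1.94), cybb, the phagocyte NADPH oxidase (-1.18), ctss2.1 (-1.16) and the scavenger receptor marco (-1.16). The score of this list was 1.07 in Pargana control fish 1 and -0.17 in Pargana control fish 2, and without fish 1 the medians were -0.17 and 0.09, with adjusted p of 0.828 and 0.265. The fall averaged over both populations on the deficient diet (-0.35) ended the same way, at 0.02, and also without any of 3 other arrays. Endothelial genes had medians of -0.32 on the deficient and -0.30 on the supplemented diet in Pargana over 14 genes (adjusted p = 0.0213 and 7.62e-04), with SLC16A1 (-0.60 and -0.92) and the vascular transcription factor FLI1 (-0.49 and -0.56) among the members, and -0.25 and -0.25 averaged over both populations. These 4 calls were each ended by leaving out any of 2 to 8 single arrays, Pargana control fish 1 among them. The adjusted p of all these tests was 0.992 with an estimated correlation.

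Eye and pineal genes rose in supplemented Pargana fish, with a median of 0.46 over 20 genes (adjusted p = 0.00163), where CRYAA (3.83) rose when adjusted over the list alone. The call ended without Pargana supplemented fish 1, at 0.18, or without Pargana control fish 1, at 0.35. In Transgenic Mosaic 1 the same list had a median of 0.21 on the deficient diet (adjusted p = 0.0397) and of -0.23 for supplemented against deficient (0.0331). Both calls ended without Transgenic Mosaic 1 deficient fish 2, at 0.05 and -0.07. That fish had saga, a photoreceptor arrestin, at 9.20 and aanat2, which serves melatonin synthesis in the pineal, at 11.33, against at most 5.16 and 9.10 in other fish. Each was also ended by 3 other single omissions. The averages over both populations, 0.36 on the deficient and 0.23 on the supplemented diet, ended without 2 and 6 single arrays, Transgenic Mosaic 1 deficient fish 2 and Pargana supplemented fish 1 giving the highest p. The adjusted p was 0.992 in each case with an estimated correlation.

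**Figure D3:**
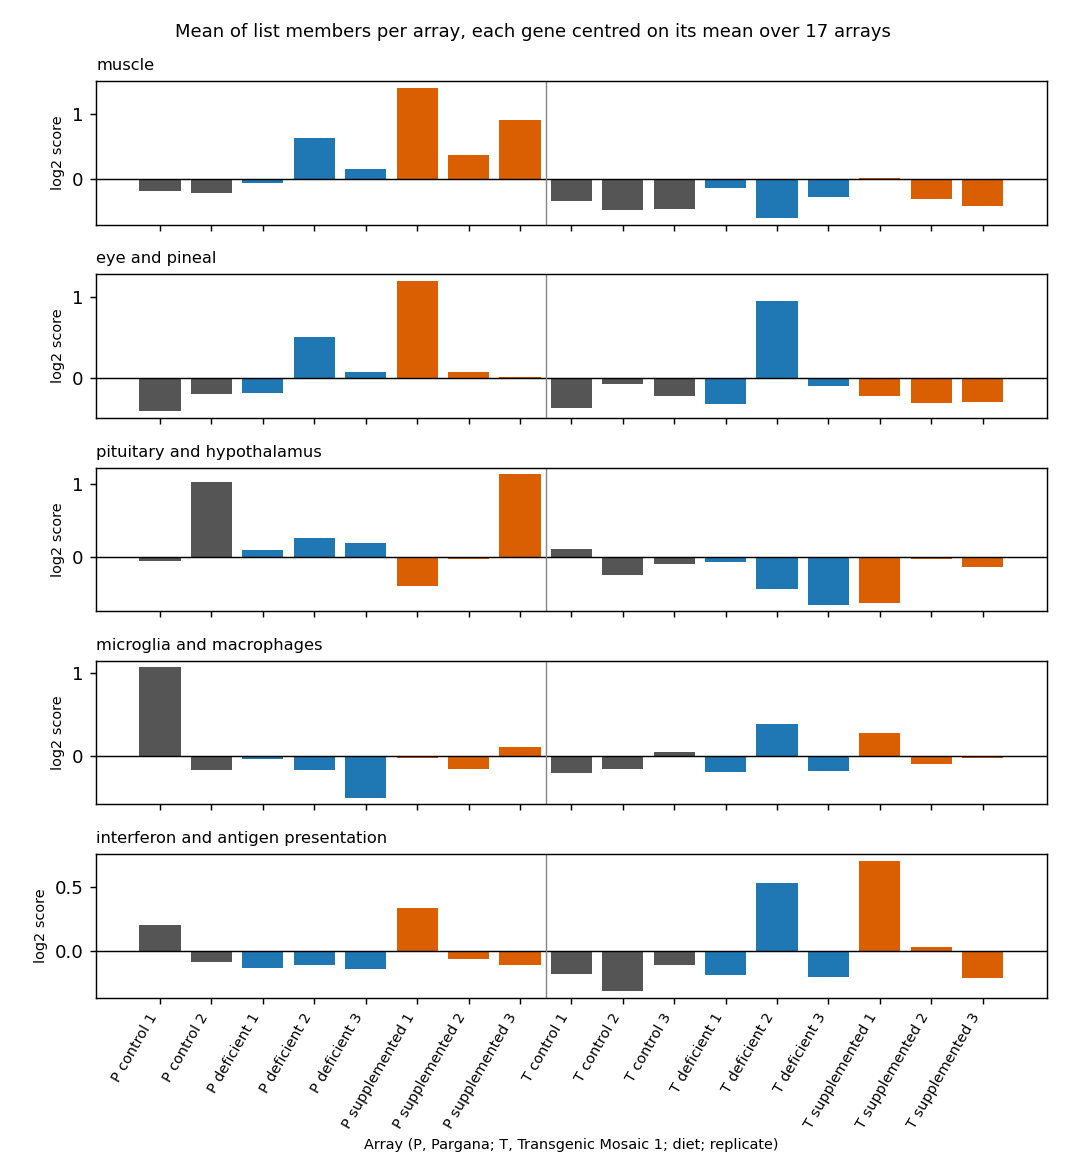
Score (y axis, log2 units) of 5 gene lists in each of 17 arrays (x axis; P, Pargana; T, Transgenic Mosaic 1; grey, control; blue, deficient; orange, supplemented), the mean over the list of each gene minus its mean over all arrays. Single arrays stand apart, such as Pargana supplemented 1 for muscle (1.41), Pargana control 1 for microglia and macrophages (1.07) and Pargana supplemented 3 for pituitary and hypothalamus (1.14).

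Interferon and antigen presentation genes rose in supplemented Transgenic Mosaic 1 fish, with a median of 0.40 and 22 of 31 genes above 0 (adjusted p = 7.62e-04). The largest values were in ifi44a1 (1.47), the proteasome subunits PSMB8 (1.36) and PSMB9 (1.31), and the antiviral GTPase mxa (1.26), none of which passed alone. The list score was 0.71 in supplemented fish 1, 0.03 in fish 2 and -0.21 in fish 3, and without fish 1 the median was 0.02 and the adjusted p 0.640. On the deficient diet the median was 0.11 (adjusted p = 0.0408), a call that 7 single omissions ended and whose median was -0.10 without Transgenic Mosaic 1 deficient fish 2. The average over both populations on the supplemented diet (0.21, adjusted p = 0.0491) was ended by any of 9 single omissions. Proliferation and neurogenesis genes fell in supplemented Pargana fish (median -0.24, 22 of 26 genes below 0, adjusted p = 9.49e-04), led by mki67, a marker of dividing cells (-1.36), and MCM6 (-1.07). That call ended without Pargana control fish 1, at -0.12. The list rose by 0.15 in Transgenic Mosaic 1 for supplemented against deficient (22 of 26 genes above 0, adjusted p = 0.00634), a call that ended without deficient fish 3. Averaged over both populations it had medians of -0.17 and -0.15 on the deficient and supplemented diets, which any of 5 and of 9 single omissions ended. With an estimated correlation the adjusted p of each was 0.992.

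Cytosolic ribosome genes fell on the deficient diet by small amounts, with medians of -0.10 in Pargana (42 of 51 genes below 0, adjusted p = 0.0274), -0.08 in Transgenic Mosaic 1 (40 of 51, adjusted p = 0.0491) and -0.08 averaged over both (44 of 51, adjusted p = 0.00199). The medians over all genes in these comparisons were -0.0295, -0.0289 and -0.0314, so part of each fall was common to all genes. The Pargana call ended without Pargana control fish 1, at -0.03, or without deficient fish 2, the Transgenic Mosaic 1 call without any of 13 arrays, and the average without Pargana control fish 1, at -0.04. Proteasome genes had a median of -0.10 in supplemented Pargana fish (23 of 27 genes below 0, adjusted p = 0.0274), which any of 4 single omissions ended. The adjusted p was 0.992 for each with an estimated correlation. For the interaction, as Transgenic Mosaic 1 minus Pargana, the microglia and macrophage list passed for the deficient (median 0.73) and the supplemented diet (0.58), both calls ending without Pargana control fish 1, at 0.24 and -0.08. For the supplemented diet the muscle (-0.84), eye and pineal (-0.60), interferon (0.27) and proliferation lists (0.19) passed too, and the last ended without Pargana control fish 1, at 0.09, while the eye and pineal and the interferon calls were each ended by any of 6 single omissions. The adjusted p of these 6 tests was 0.992 with an estimated correlation. In all, 35 of the 319 tests passed with the preset correlation, 0 with the estimated correlation and 0 with fry, and 21 of the 29 lists passed with the preset correlation in none of the 11 comparisons. Fry's mixed test, which ignores direction, passed in 21 of the 319 tests. Of these, 18 were for the population difference, 1 for supplemented against control Pargana fish and 2 for the average of the supplemented diet.

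The lists that passed in none had lowest adjusted p of 0.0523 for heat shock (median -0.12), 0.0559 for oligodendrocytes and myelin (-0.13), 0.0858 for the methionine cycle and transsulfuration (0.06), 0.0899 for the steroid and stress axis (-0.22), 0.0961 for pituitary and hypothalamus (-0.37), 0.103 for hindbrain and cerebellum (-0.13), 0.132 for erythrocytes (-0.27), 0.154 for midbrain and tectum (-0.11), 0.167 for immediate early genes (-0.10), 0.187 for telencephalon (0.05), 0.243 for radial glia and astrocytes (0.17), 0.255 for monoamine neurons (-0.17) and 0.279 for the circadian clock (-0.16). For the unfolded protein response it was 0.377 (0.00), for selenoproteins 0.405 (-0.08), for thyroid hormone 0.472 (0.25), for the selenium-sensitive selenoproteins 0.509 (-0.12), for antioxidant and glutathione genes 0.524 (0.07), for selenocysteine machinery 0.546 (0.03), for oxidative phosphorylation 0.562 (-0.03) and for neurons of GABA and glutamate 0.738 (-0.01). Each median is that of the comparison with the lowest p.

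Whether the diets moved the same genes in both populations was asked by correlating the log2 changes across genes, which are not independent replicates. Between Pargana and Transgenic Mosaic 1, r was 0.033 for deficient minus control (rho 0.078), -0.055 for supplemented minus control (rho -0.052) and -0.052 for supplemented minus deficient (rho -0.045). In 100 permutations of the diets within populations, p was 0.65, 0.49 and 0.63 for r and 0.45, 0.55 and 0.66 for rho, and the adjusted p over the 3 values of r was 0.65. Without Pargana control fish 1 the second r was 0.063.

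Within a population the deficient and supplemented diets were compared with the same control fish, so part of any overlap comes from those fish. In Pargana 4 of the 6 and 5 genes were shared in the same direction, in Transgenic Mosaic 1 4 of the 4 and 13, and averaged over both 4 of the 5 and 7. Simulated unchanged groups against the same controls shared 0.02, 0 and 0.01 genes on average, at most 1, and independent lists of these sizes would share 0.000959, 0.00204 and 0.00141. The simulated values had only independent noise around equal means, so few genes could pass and a shared count near 0 was fixed in advance. They hold no on or off differences of control fish, so these counts do not tell whether the control fish gave the overlap. The changes correlated at r = 0.640, 0.643 and 0.653 across genes, where the simulations gave 0.601, 0.502 and 0.558. The covariances were 0.0881, 0.0542 and 0.0358 against simulated values of 0.0609, 0.0407 and 0.0255. The control groups of 2 and 3 fish were too small to be split.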

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

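The tests of control fish set apart and of list shifts that follow single arrays were chosen after those results were seen, as were the gap of 1.5 log2 units, taken after wider gaps had been tried too, and the limits of p under 0.001 and 10 genes in the test of neighbours. For the population difference the splits were chosen before the data were examined, and the test of neighbouring genes and the fits with marker scores after, with their limits set before their own values were seen; no limit was set for the covariates or for the deficient diet alone.

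A first pattern is that the genes whose response to diet differed between the populations set the control fish of 1 population apart, with an adjusted p of the interaction in limma of 1.41e-05 for UBE2G1, 1.41e-05 for ENSDARG00000078938, 0.0103 for ENSDARG00000091965, 0.00319 for si:dkey-58f10.8 and 1.41e-07 for ENSDARG00000095735. In Pargana 5 features set the 2 control fish apart from all others by a gap of 1.5 log2 units, and 12 features did so for another pair, so on or off differences between single fish that fall on the control fish by chance may account for them. In Transgenic Mosaic 1, 4 features set the 3 control fish apart, all of them called in a diet comparison, and at most 3 any other trio. There were 84 possible trios and 21 features that set a trio apart, so an even spread would give 0.25 per trio. For the 28 possible Pargana pairs an even spread would give 2.14. The control trio had the highest count, but another trio with 3 shows that the spread was not even. The 4 features therefore cannot be told apart from chance differences between fish. For supplemented against control Transgenic Mosaic 1 fish, 7 pairs of genes with p under 0.001 lay within 10 genes of each other and had the same sign, where 1000 shuffles of the gene order gave a median of 1 and never as many. Chromosome segments shared by the supplemented fish may therefore account for these pairs. An effect of diet on neighbouring genes was not tested and stays open. The deficient diet against the same control fish gave 0 pairs from 19 features, and supplemented against deficient Transgenic Mosaic 1 fish 0 from 10. The shuffles had a median of 0 in both, and segments of the supplemented fish alone would not show in the former, so these counts do not decide it. The Pargana diets against control gave 2 and 2 pairs (58 and 252 of 1000 shuffles as many), and supplemented against deficient Pargana fish gave 0.

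A second pattern is that gene list shifts follow single arrays. In Pargana supplemented fish 1, which has the highest muscle score, 89.47% of the muscle list (17 of 19 genes) lay above their means. The 5 pituitary hormone genes examined (gh1, prl, TSHB, POMC and fshb) all had their 2 highest values in Pargana control fish 2 and Pargana supplemented fish 3, with gh1 at 12.04 and 11.31. These arrays were picked by the scores of the same genes, so the values do not decide whether RNA of muscle or of pituitary in single dissections is the source, and both stay open. The fall of microglia and macrophage genes in deficient Pargana fish was -0.78 with both control fish and -0.17 (-0.1688) without Pargana control fish 1. That fish has the highest score of this same list, 1.07, and is 1 of 2 control fish, so a smaller fall without it follows from the choice. Many macrophage transcripts in that fish may account for the fall, but this value does not decide it. A response to diet in single fish was not tested and stays open.

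The last pattern is the size of the population difference: of 100 splits of the arrays only the real one gave as many genes as 2089, so 1 split was as large and the highest other gave 303, and chance is excluded. Without the 5 arrays of high marker scores, in a fit with no Pargana control and 1 Pargana supplemented fish and so no average over all 3 diets, the differences of the called genes had a median ratio of 1.04 to those with them (quartiles 0.833 and 1.24), 2086 of 2089 kept their sign and 779 genes passed, as standard errors grew by a median of 1.45 times. With marker scores as covariates 222 genes passed, 182 of them shared, with a median ratio of 1.02 (quartiles 0.734 and 1.29) and standard errors 1.92 times as large, and within the deficient diet without its 1 such array the ratio was 1.00 (lower quartile 0.691, 2045 of 2089 with the same sign), so the sizes argue against RNA of neighbouring tissue or macrophages in those arrays as the whole cause, though not for each gene. Neighbouring genes had a Spearman rho of 0.0766, above 98 of 99 reassignments of the arrays (highest 0.0779), so inherited chromosome segments, through expression or probe mismatches, cannot be told apart from other inherited differences. A biological difference between the populations stays open.

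For gene lists the interaction, as Transgenic Mosaic 1 minus Pargana, had medians of 0.7278 for microglia and macrophages on the deficient diet and 0.5793 on the supplemented diet. On the supplemented diet it was 0.2734 for interferon and antigen presentation, -0.6022 for eye and pineal, -0.841 for muscle and 0.1906 for proliferation and neurogenesis. Without Pargana control fish 1 the microglia and macrophage medians were 0.24 and -0.08 and the proliferation call ended, at 0.09, and any of 6 single omissions ended the eye and pineal and the interferon calls. With an estimated correlation the adjusted p of all 6 was 0.992.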

How the results depend on the processing

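The marker score covariates and the fit without arrays of high marker scores were chosen after the data were seen. The cause of a change was not tested unless a sentence names one. Leaving out a Pargana control fish leaves 1 fish there, which is assumed to vary like the other groups. Of the named genes past the threshold, 871 of the values without single arrays kept their call and 47 lost it, and under other settings 389 kept and 63 lost it, with no change of direction. For called lists the numbers were 481 kept, 110 lost and 4 reversed without single arrays, and 93 kept and 82 lost under other settings. Signal over background was not used here, so what it limits was not examined.

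With marker scores as covariates, 222 genes passed for the population difference, 1 for deficient and 2 for supplemented against control in Pargana, 0 for supplemented against deficient in Transgenic Mosaic 1, and 3 and 1 for the averages of the deficient and the supplemented diet. Without the arrays of a high marker score 779 passed for the population. Quantile normalization again gave 1166 genes higher and 1019 lower in Transgenic Mosaic 1, where the values as deposited gave 1002 and 1087. With the lowest quartile of mean value left out, 3 passed for the deficient Pargana diet and 3 for the average of the supplemented diet. With 1 feature per symbol, which tests fewer features, 1 passed for the supplemented Pargana diet and 3 and 4 for the averages. With only the 2 groups compared, which uses fewer arrays, 1 passed for the deficient Pargana diet. With only the arrays of that population, 2 and 1 passed for the Pargana diets and 5 for the supplemented Transgenic Mosaic 1 diet. With array weights 34 passed for the latter and 11 for the average of the supplemented diet. The model without interaction gave 0 for both averages. For supplemented against deficient Transgenic Mosaic 1 fish 0 genes passed in limma after quantile normalization, without the lowest quartile, with 1 feature per symbol, with trended and robust moderation, with the 2 groups alone and with that population alone; the lowest quartile and the 1 feature per symbol settings leave its 1 gene untested, so their 0 is fixed by construction. Of the list shifts 0 passed with an estimated correlation and 0 with fry.

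Without single arrays the counts ran from 1590 to 2136 for the population, 3 to 198 and 2 to 162 for the deficient and supplemented diets in Pargana, 0 to 16 for supplemented against deficient there, 4 to 10 and 8 to 26 for the diets in Transgenic Mosaic 1 and 0 to 2 between them. They ran from 5 to 98 and 6 to 90 for the averages, 5 to 87 for the interaction and 13 to 47 for list shifts. The counts of 198, 162, 98, 90 and 87 were all without Pargana control fish 2, and 13 without Pargana control fish 1. Correlations ran from -0.035 to 0.099, -0.130 to 0.063 and -0.107 to -0.0089. The microglia median for the supplemented diet in Pargana ran from -1.22 to 0.0909, for the average of the deficient diet from -0.68 to 0.0187 and for the interaction on the supplemented diet from -0.0777 to 1.25, each turning without Pargana control fish 1. The interferon median for the deficient diet in Transgenic Mosaic 1 ran from -0.10 to 0.23, turning without Transgenic Mosaic 1 deficient fish 2.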

Other observations

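The tests of this part, splits of the arrays, were chosen before the data were examined; the hormone values were looked at after. The gene oxt, which encodes the fish counterpart of oxytocin, was at 10.22 and 10.32 log2 units in the Pargana control fish, 7.91 in Transgenic Mosaic 1 control fish 2 and 7.20 in deficient fish 3, and between 10.76 and 13.52 in the other fish. The gene avp, of the vasopressin family, was lowest in the same deficient fish, at 9.31. The circadian clock list had scores of -0.34 in Pargana control fish 1 and 0.28 in Pargana control fish 2.

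Other splits of the same fish into groups of the same sizes were counted. For the average of the deficient diet, 17 of 100 splits gave at least the 5 genes of the real split, the highest other 9, and for the supplemented diet 10 of 100 gave at least 7, so chance is not excluded for either. The highest other split for the supplemented diet gave 71, so the samples may hold a structure other than the diets, which was not tested. The list shifts in the diet and interaction comparisons, adjusted over these 290 tests alone, numbered 35, 55 of 100 splits gave as many and the highest other gave 62, so chance is not excluded. Within populations 3 fish against 3 make 10 splits, too few for a share under 0.05. For supplemented against deficient Pargana fish the real split gave 0 genes and the highest other 16; all 10 splits give at least 0, so that count says nothing. Of the 10, 2 gave at least 4 for the deficient Transgenic Mosaic 1 diet (highest other 5), 1 gave at least 13 for its supplemented diet (highest other 1) and 7 gave at least 1 between them (highest other 4). The Pargana comparisons with the 2 control fish were not split.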
